A study of Homo sapiens with 19 samples.

How the data were processed

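RNA of Jurkat T cells was measured on 19 Illumina bead arrays in 10 groups. Per the labels' protocols, cells were kept with the stimuli for 1, 4 or 8 h at 37C in a buffered salt solution, RNA was extracted with RNeasy Plus, and biotin-labelled cRNA was made with TargetAmp-Nano. The authors deposited the values used here as linear intensity per probe and array. GenomeStudio 1.8 is named per the submitters' processing notes. All arrays share 1 minimum (43.2) and 1 maximum (39841), and the 75th percentile was 126.3 or 126.4 on 18 arrays and 124.1 on the calcium-free 8 h array. The values therefore appeared already normalized between arrays by quantiles, as read from the values themselves. Background had not been subtracted as far as the values show, and the remaining steps are not given in the sources used here. A second table of non-normalized signals has 38 columns (19 signals and 19 detection p-values) named by chip, which no label ties to a sample, and was not used. The number of arrays limits the precision. On 18 arrays 33.9% to 34.4% of probes stood above background, a share that the common distribution of values sets.

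The plan had assumed non-normalized signals with detection p-values, so the planned neqc step was replaced. The background of each array was modelled from the mode of its values (78.7 to 79.0) and the SD of the values on the low side, and normexp from limma 3.58.1 in R 4.3.3 removed it. An offset of 16 was added, and log2 values were taken. A probe counted as above background above the 99th percentile of that model (99.3 to 99.9), and 22613 of 47317 probes that did so on at least 2 arrays were kept. On an array whose rank correlations with all other arrays lay under 0.5, no probe was counted as above background. The calcium-free 8 h array fell under that rule. The given probe table has 1 symbol for 30111 probes, several for 8 and lists no gene for 17198, and 30072 matched the RefSeq gene table by Entrez identifier. Of the kept probes 16287 had a symbol. The brightest probe stood for each of 12390 genes, 3076 of which had more than 1 kept probe.

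Genes were tested with limma (lmFit and eBayes, two-sided) in 1 fit of all 19 arrays with a mean per group, 9 residual degrees of freedom and no replicate block, with the Benjamini-Hochberg adjustment over all genes of a comparison and a threshold of 0.05. The prior SD was 0.202 on the log2 scale with 4.37 prior degrees of freedom. An exact permutation test of 2 against 2 arrays cannot go below p = 0.333, so gene p-values come from limma alone. Comparisons were full stimulation against calcium-free stimulation (calcium effect) and against PMA with calcium (ionomycin effect), PMA with calcium against calcium-free stimulation, each stimulation against untreated cells, and the change of the calcium effect between times. Changes of the ionomycin effect over time were added after seeing the data. In addition 18 gene lists fixed in advance were tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists, and again with the correlation estimated for each list.

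Genes were named by a rule: in the calcium and ionomycin effects the 8 largest rises and falls at 4 h and the 5 largest at 1 and 8 h, in the other comparisons the 4 largest, among genes past the threshold whose groups did not overlap; up to 4 members of each list per comparison; and always IL2, TNF, NFKBIA, NFKBIE, TNFAIP3, CD69, EGR1, EGR2, EGR3, FOS, IL2RA, CXCL8, RCAN1, NR4A1, HSPA5, DDIT3, STIM1, ORAI1 and GAPDH. Symbols starting with LOC, HS., FLJ or KIAA were left out of the largest.

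The steps were tested on simulated data for the calcium effect at 4 h, with 200 of 12390 genes changed in each of 20 draws. Changes of 0.5, 1, 2 and 4 on the log2 scale were recovered in 5.3%, 63.1%, 98.4% and 100% of genes, and 5.14% of calls were false. The NF-kB list, shifted by 0.4 besides these 200 genes, was called in 20 of 20 draws. Noise was drawn independently for each gene and array, so these rates do not cover deviations that arrays share across genes.

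Alternatives were no background correction, cyclic loess, scaling to the 75th percentile, an offset of 50, no filter, a filter on at least 10 arrays, the mean of a gene's probes, a replicate block, array weights, a trend with robust settings, only the arrays compared, and leaving out each replicate. Normexp with its background estimated from all values and a run without the calcium-free 8 h array were chosen after seeing the data.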

Results

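Jurkat T cells, a human leukaemic T cell line, were stimulated in a buffer at 37C and their total RNA was measured on Illumina bead arrays. There were 3 stimulations. The first was PMA, a phorbol ester that activates protein kinase C, at 200 nM with 2 mM calcium outside the cells (PMA with calcium). The second added 1 µM ionomycin, an ionophore that raises cytosolic calcium (full stimulation). The third kept PMA and ionomycin but had 0 mM calcium and 0.25 mM of the chelator EGTA (calcium-free stimulation). Each was sampled at 1, 4 and 8 h. Untreated cells were listed at 0 mM calcium. With them this gave 10 groups and 19 arrays, 2 arrays in every group except the calcium-free 8 h group, which had 1.

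On 18 arrays 33.9% to 34.4% of the 47317 probes stood above background. The common distribution of values sets that share, so it does not measure array quality. Rank correlations between these arrays lay between 0.751 and 0.850. The calcium-free 8 h array ranked its probes unlike all the others (rank correlation 0.031 to 0.105). It read 100.4 for EEF1A1, a translation factor, and 105.5 for GAPDH, a glycolytic enzyme, where the other 18 arrays read 28699 to 39841 and 15511 to 22756. Between replicates the SD of the log2 difference across genes ran from 0.291 in PMA with calcium at 8 h to 0.453 in full stimulation at 1 h. Precision is limited by the number of arrays, and every p-value here measures only the spread between these samples. Values are mean intensity ± SD with n = 2 arrays per group. Fold changes are on a log2(normexp + 16) scale, given ± SE, and understate the changes of dim genes. Where a gene was not above background on any array of the dimmer group, its fold change is a lower bound, made on the same scale by setting each dim array to the lowest value that counted as above background there. The bound holds only once the background is removed. The intensities printed still hold a background of 78.7 to 79.0, so their ratios differ from these folds. Groups, gene lists, the rule for naming genes and the comparisons in this section were fixed before the data were examined. The checks against replicate 1 and replicate 2 of full stimulation at 1 h were chosen after the results were seen. Set tests of lists kept their call with an estimated correlation unless a value is given.

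The calcium effect at 1 h asked what calcium outside the cells added to PMA and ionomycin. Only the calcium-free group of this pair held EGTA, so calcium and the chelator cannot be told apart in the calcium effect at any time. TNF, which encodes an inflammatory cytokine, stood 2.75 ± 0.17 higher on the log2 scale under full stimulation than under calcium-free stimulation (5132 ± 270 against 815 ± 6.93, adjusted p = 4.4e-06). Untreated cells read 120.4 ± 5.52. NFKBIA, which encodes the inhibitor that NF-kB itself induces, stood 1.27 ± 0.13 higher (16250 ± 166 against 6785 ± 443, adjusted p = 1.7e-04). The dendritic and T cell marker CD83, the cytokine gene LTA and the costimulatory receptor ICOS also rose, by 1.58, 1.57 and 2.36 on the log2 scale. A probe named for CCL4L1, whose family members share sequence so that the source of its signal is uncertain, rose by 3.05 ± 0.23 (344 ± 77.1 against 95.8 ± 7.21). CD69 stood 1.08 ± 0.28 higher without passing (adjusted p = 0.076). The immediate early genes EGR1 and FOS differed by -0.17 (adjusted p = 0.61) and 0.17 (adjusted p = 0.72), and IL2 was not above background in either group.

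Of 33 measured NF-kB pathway and target genes in this comparison, 10 rose, 1 fell and 22 did not pass, and 14 rose and 1 fell when adjusted over the list alone. As a set they stood higher than other genes (camera adjusted p = 1e-06). AP-1 and immediate early genes did so too (7 of 29 rose and 0 fell, 10 and 1 adjusted over the list alone, adjusted p = 3.8e-06). TRIB1, a regulator of transcription factor degradation, stood at least 4.21-fold higher. Of 17 ERK feedback genes, which damp growth factor signalling, 3 rose, among them PHLDA1 by 1.85 (5 adjusted over the list alone, set adjusted p = 3.8e-04). Of 20 NFAT target and T cell cytokine genes 3 rose (5 adjusted over the list alone, set adjusted p = 3.1e-04). Of 21 interferon response genes 1 rose (3 adjusted over the list alone, set adjusted p = 0.017), a call lost at adjusted p = 0.051 with an estimated correlation, at 0.056 without replicate 1 of full stimulation and at 0.1 without replicate 1 of the calcium-free group. Heat shock genes, which encode protein-folding chaperones, stood lower as a set (median -0.24, adjusted p = 0.0064), although 0 of 13 passed singly over all genes (4 lower adjusted over the list alone). This call was lost at adjusted p = 0.17 with an estimated correlation and at 0.26 without replicate 2 of full stimulation at 1 h.

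In all, 130 of 12390 genes differed in the calcium effect at 1 h, 74 higher and 56 lower with calcium, 51 and 41 of them by at least 2-fold. Lower genes were the majority without background correction (190 higher and 229 lower), with an offset of 50 (187 and 212), with a trend and robust settings (216 and 224) and with a replicate block (154 and 226). The count was 380 with a replicate block, 235 with a filter on 10 arrays, 47 with array weights and 2 with only the arrays compared. The 56 lower genes included CDCA3, a cell cycle gene (-2.11 ± 0.34, 98.5 ± 21.8 against 219.2 ± 44.4, adjusted p = 0.009), and CIRSR (at least 2.35-fold lower, adjusted p = 0.0058). Of these 56, 50 were brighter on replicate 1 than on replicate 2 of full stimulation, whereas 50 of the 74 higher genes were dimmer there. The count was 563 without replicate 1 and 26 without replicate 2 of full stimulation, and 28 without replicate 1 and 65 without replicate 2 of the calcium-free group. CDCA3 and CIRSR lost their calls without replicate 2 of full stimulation or replicate 1 of the calcium-free group. Of the named genes, 11 of the 25 that passed kept their call without each array in turn. TNF, NFKBIA, CD83, LTA, ICOS, PHLDA1, TRIB1 and CCL4L1 were among them.

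The calcium effect at 4 h asked the same question later. IL3, which encodes a growth factor for blood progenitors, was 25.7-fold higher with calcium (2330 ± 51.1 against 153 ± 18.2, log2 4.68 ± 0.29, adjusted p = 8.3e-07). Untreated cells read 75.85 ± 12.5. The chemokine CCL20 rose by 3.48 ± 0.18 (644 ± 76.3 against 116 ± 12.7), and probes of the CCL3 family, which cannot be assigned with certainty to CCL3, CCL3L1 or CCL3L3, rose by 3.84 to 4.12. TNF was 1.83 ± 0.17 higher (adjusted p = 2.7e-05) and NFKBIA 1.74 ± 0.13 higher (7716 ± 450 against 2351 ± 201, adjusted p = 2.7e-06). IL2, the T cell growth factor, remained near background at 119 ± 2.33 against 80.3 ± 4.1, at least 1.51-fold higher (adjusted p = 0.001). Falling genes included KLF2, a factor that keeps T cells quiescent (-2.51 ± 0.18, 172.5 ± 8.2 against 689 ± 65.4), the ubiquitin ligase adaptor SPSB1 (-2.76 ± 0.20) and the lipid receptor LPAR6 (-2.12).

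At 4 h, 11 of 20 NFAT target and T cell cytokine genes rose with calcium and 9 did not pass (11 rose and 1 fell adjusted over the list alone, median 1.17, set adjusted p = 3.4e-16). TNFSF14 rose by 2.61 and XCL1 at least 3.92-fold. Of 33 NF-kB pathway and target genes 9 rose and 1 fell (11 and 1 adjusted over the list alone, median 0.21, set adjusted p = 3.1e-06), among them CXCL8, a neutrophil chemoattractant, by 2.48. Of 21 interferon response genes 3 rose (5 adjusted over the list alone, set adjusted p = 6.4e-04), with the antiviral GTPase GBP2 up by 3.32 and the peptide transporter TAP1 by 1.03. Of 19 T cell activation surface markers 6 rose and 2 fell (7 and 5 adjusted over the list alone, set adjusted p = 0.019), a call lost at adjusted p = 0.082 with an estimated correlation and at 0.069 without replicate 1 of the calcium-free group. Among them, ICOS rose by 1.83 and CD27 at least 3.84-fold. Of 17 glycolysis and hypoxia genes 2 fell (2 adjusted over the list alone, set adjusted p = 0.037), lost at adjusted p = 0.15 with an estimated correlation and at 0.14 without replicate 1 of the calcium-free group or 0.13 without replicate 2 of full stimulation.

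Lists without a set call in the calcium effect at 4 h were these. AP-1 and immediate early genes split, 5 of 29 higher and 3 lower (6 and 9 adjusted over the list alone, set adjusted p = 0.32). MYC stood 1.73 higher than under calcium-free stimulation, although below its untreated level. Of 23 unfolded protein response genes 1 rose (1 adjusted over the list alone, set adjusted p = 0.066) and HSPA5, the chaperone BiP, differed by 0.02 (adjusted p = 0.97). Of 19 store-operated calcium entry and calcium handling genes 1 rose and 1 fell (2 and 3 adjusted over the list alone, set adjusted p = 0.46). STIM1 and ORAI1, the sensor and the pore of store-operated entry, differed by 0.21 (adjusted p = 0.71) and 0.53 (adjusted p = 0.21). RCAN1 stood at -0.49 (adjusted p = 0.075), FOS at -0.67 (adjusted p = 0.067) and IL2RA at 0.71 (adjusted p = 0.12). NFKBIE (0.34, adjusted p = 0.23), TNFAIP3 (0.16, adjusted p = 0.74) and EGR1 (-0.33, adjusted p = 0.25) did not pass. EGR3 (0.54, adjusted p = 0.52) and NR4A1 (0.22, adjusted p = 0.75) did not pass either, and EGR2 had no probe with that symbol. EGR3 and NR4A1 stayed near background, with a highest intensity of 132.9 and 130.5 on the 18 arrays with signal. A lack of response therefore cannot be read from either gene. CD69 stood 1.47 ± 0.28 higher (adjusted p = 0.0082), but lost its call without replicate 1 of full stimulation or replicate 2 of the calcium-free group.

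Among the remaining lists in the calcium effect at 4 h, ERK feedback genes had 1 of 17 higher and 1 lower (the same adjusted over the list alone, set adjusted p = 1). The T cell receptor and T lineage list had 3 of 22 higher and 3 lower (4 and 5 adjusted over the list alone, adjusted p = 0.86), with TOX at least 3.51-fold higher. ATF4 and amino acid response genes had 1 of 22 higher and 1 lower (3 and 1 adjusted over the list alone, adjusted p = 0.12). Cell cycle genes had 1 of 29 higher and apoptosis and growth arrest genes 2 of 16 (the same adjusted over the list alone, adjusted p = 0.86 each). Metallothionein and zinc response genes had 1 of 8 higher (1 adjusted over the list alone, adjusted p = 0.14). Past the limma test were 0 of 15 sterol synthesis genes (adjusted p = 0.86), 0 of 13 heat shock genes (1 higher adjusted over the list alone, adjusted p = 0.23), 0 of 13 other blood cell markers (1 lower adjusted over the list alone, adjusted p = 0.15) and 0 of 11 housekeeping genes (adjusted p = 0.32). GAPDH differed by 0.04 (adjusted p = 0.95).

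Altogether 531 genes differed at 4 h, 286 higher and 245 lower with calcium, 141 and 109 of them by at least 2-fold. The count fell to 301 and 240 without replicates 1 and 2 of full stimulation, and to 341 and 218 without replicates 1 and 2 of the calcium-free group. It was 127 with only the arrays compared, and lower genes led without background correction (339 higher and 350 lower) and with an offset of 50 (358 and 359). Of 46 named genes that passed, 32 kept their call without each array, and besides CD69 these include the genes named for a rise or fall at 4 h here.

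Whether the calcium effect at 4 h differed from that at 1 h was tested as an interaction. The effect of calcium was larger at 4 h for IL3 (by 3.37 ± 0.42 on the log2 scale, adjusted p = 0.001), CCL20 (2.35 ± 0.25), GBP2 (2.91 ± 0.30) and the costimulatory receptor CD27 (2.61 ± 0.35). It shifted downward, to a fall with calcium at 4 h, for KLF2 (-2.12 ± 0.26, adjusted p = 0.001), SPSB1 (-2.92 ± 0.29), the phosphatase DUSP5 (-1.93 ± 0.23, adjusted p = 8.5e-04) and FOSB (-1.92 ± 0.27). For NFKBIA (0.47, adjusted p = 0.19) and TNF (-0.93, adjusted p = 0.058) the difference did not pass. NFAT target and T cell cytokine genes shifted up as a set (median 0.55, adjusted p = 3.9e-06; 8 of 20 genes higher, 8 higher and 2 lower adjusted over the list alone). AP-1 and immediate early genes shifted down (median -0.70, adjusted p = 1.3e-04; 2 of 29 higher and 8 lower, 2 and 15 adjusted over the list alone). NF-kB genes showed no set shift (median -0.09, adjusted p = 0.77; 1 of 33 higher and 4 lower, 4 and 8 adjusted over the list alone). In all 347 genes passed, 189 with a higher and 158 with a lower effect at 4 h. That count was 650 and 165 without replicates 1 and 2 of full stimulation at 1 h, and 124 and 223 without those of the calcium-free 1 h group. It was 201 and 212 without those of full stimulation at 4 h, and 218 and 131 without those of the calcium-free 4 h group. It was 611 without background correction, 604 with an offset of 50, 592 with a trend and robust settings, 538 with a replicate block, 225 with array weights and 83 with only the arrays compared. Each gene named here as passing kept its call.

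**Figure D1:**
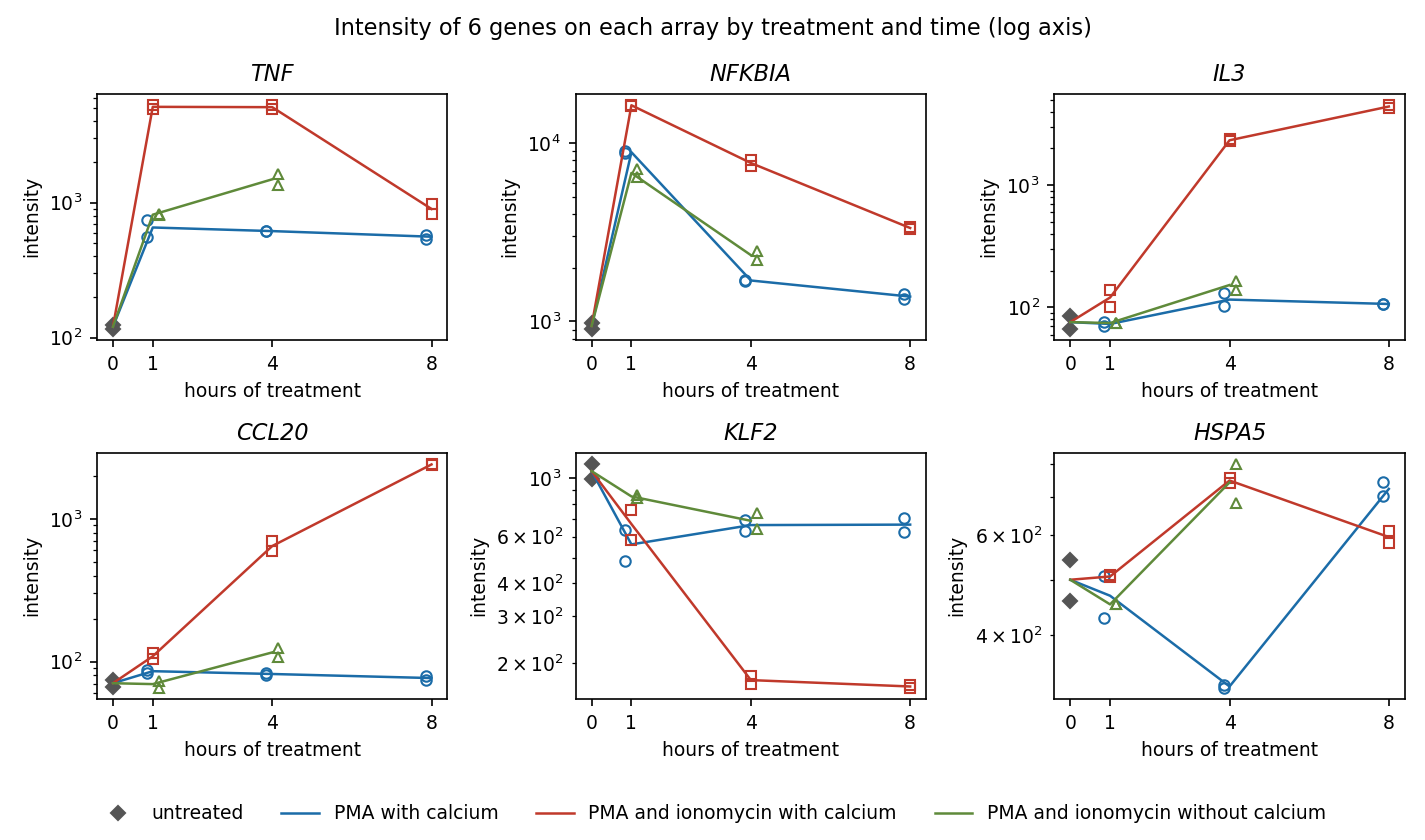
Intensity (log axis) of 6 genes on each array against hours of treatment, with open symbols for single arrays, lines through group means and diamonds for the untreated arrays. Untreated arrays are drawn at 0 h, where each line starts, although no label gives them a time. The calcium-free 8 h array is not drawn. TNF stood at 5132 and 5103 after 1 and 4 h of full stimulation and at 899 after 8 h, while IL3 stood at 4399 and CCL20 at 2402 at 8 h.

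The ionomycin effect at 1 h compared full stimulation with PMA and calcium alone, and so asked what the ionophore added. TNF was 3.12 ± 0.17 higher on the log2 scale with ionomycin (5132 ± 270 against 655 ± 133, adjusted p = 9.1e-07). FOSB, an AP-1 subunit, rose by 1.78 ± 0.19 (3523 ± 281 against 1075 ± 186, adjusted p = 6.6e-04), and ICOS by 1.88. The CCL4L1 probe rose at least 7.46-fold and the CCL3L3 probe at least 2.74-fold, with the same uncertainty about family members. HES1, a transcriptional repressor downstream of Notch, fell by 1.40 ± 0.18 (412 ± 70.1 against 973 ± 16, adjusted p = 0.0034) and PLEKHF1 by 1.15. CD69 and CXCL8 stood 1.49 and 1.69 higher without passing (adjusted p = 0.056 each), although CXCL8 passed without replicate 1 (0.014) or replicate 2 (0.0067) of PMA with calcium or replicate 2 of full stimulation (0.043). TNFAIP3, an NF-kB target that ends signalling, differed by 0.08 (adjusted p = 0.88).

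NFAT target and T cell cytokine genes were the set that shifted in the ionomycin effect at 1 h (2 of 20 rose, 7 adjusted over the list alone, set adjusted p = 5.5e-08). Of 33 NF-kB pathway and target genes 2 rose and 31 did not pass (6 rose and 5 fell adjusted over the list alone), and the set did not shift (median -0.02, mean 0.11, adjusted p = 0.6). TNF belongs to both lists, so it counts in each of them here and in every other comparison. NFKBIA stood 0.88 ± 0.13 higher (adjusted p = 0.011), but lost its call without replicate 2 of PMA with calcium or replicate 1 of full stimulation. In all 23 genes passed, 17 higher and 6 lower, against 1501 at an unadjusted p under 0.05. The count was 11 without replicate 2 and 38 without replicate 1 of PMA with calcium, and 13 without replicate 1 and 134 without replicate 2 of full stimulation. It was 41 without background correction, 43 with an offset of 50, 54 (30 higher and 24 lower) with a trend and robust settings, 9 with array weights and 2 with only the arrays compared. Of 17 named genes that passed, 8 kept their call without each array in turn, and these include TNF, FOSB, ICOS, CCL4L1, CCL3L3, HES1 and PLEKHF1.

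The ionomycin effect at 4 h compared the same treatments later. The CCL4L1 probe was at least 194-fold brighter with ionomycin (7204 ± 150 against 88.5 ± 15.7), and those of CCL3L3 and CCL3 at least 115-fold and 59.5-fold, again uncertain within the family. IL3 rose by 5.48 ± 0.29 (2330 ± 51.1 against 116 ± 19.9, adjusted p = 5.6e-08), GZMB, which encodes a killer-cell protease, by 4.86 ± 0.25 (965 ± 87.5 against 92.05 ± 17.2), and IFNG by 3.77 ± 0.24 (696 ± 41.7 against 111 ± 15.3, adjusted p = 4.5e-07). TNF was 3.19 ± 0.17 higher (5103 ± 215 against 616 ± 4.81) and NFKBIA 2.23 ± 0.13 higher (7716 ± 450 against 1695 ± 7.35). Genes that fell included KLF2 (-2.46 ± 0.19), the inhibitory receptor CD300A (at least 5.63-fold lower), the uridine phosphorylase UPP1 (-2.70) and CCR7, a lymph node homing receptor (-1.60). CD247 and LAT, which carry the T cell receptor signal, fell by 0.94 and 0.96.

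Of 33 NF-kB pathway and target genes 12 rose and 2 fell with ionomycin at 4 h (19 and 6 adjusted over the list alone, median 0.55, set adjusted p = 1.2e-12). Of 20 NFAT target and T cell cytokine genes 10 rose and 0 fell (10 adjusted over the list alone, median 0.90, set adjusted p = 1.2e-19). Of 23 unfolded protein response genes 6 rose and 17 did not pass (6 adjusted over the list alone, median 0.27, set adjusted p = 6.9e-08): HSPA5 by 1.39 ± 0.15 (748 ± 11.2 against 325.5 ± 2.55, adjusted p = 6.1e-05), the stress factor DDIT3 by 1.12 and the co-chaperone SDF2L1 by 0.96. In PMA with calcium at 4 h HSPA5 itself stood below its untreated level of 501 ± 59 (-0.73, adjusted p = 0.0046), a call lost without untreated replicate 2 (0.06). T cell activation surface markers rose as a set (5 of 19 higher and 1 lower, 8 and 4 adjusted over the list alone, adjusted p = 0.004), with SLAMF1 at least 3.33-fold higher, and so did interferon response genes (2 of 21, 2 adjusted over the list alone, adjusted p = 0.0044).

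Weaker set shifts at 4 h concerned 3 more lists. ATF4 and amino acid response genes stood higher (median 0.22, 0 of 22 rose and DDIT4 fell by 1.59, 1 lower adjusted over the list alone, adjusted p = 0.024), and lost the call without replicate 2 of PMA with calcium (0.076) or replicate 1 or 2 of full stimulation (0.068 and 0.07). Cell cycle genes stood lower (median -0.15, although 1 of 29 rose, the cyclin CCND2 by 1.35, 1 adjusted over the list alone, adjusted p = 0.022), and lost it without replicate 2 of PMA with calcium (0.095) or replicate 1 of full stimulation (0.084). Apoptosis and growth arrest genes stood higher (3 of 16 rose, 4 and 1 lower adjusted over the list alone, adjusted p = 0.024), among them GADD45A by 2.54, a call lost at adjusted p = 0.052 with an estimated correlation and at 0.14 without replicate 1 of full stimulation. Altogether 365 genes passed, 197 higher and 168 lower, 138 and 88 of them by at least 2-fold. The count was 193 and 220 without replicates 1 and 2 of PMA with calcium and 214 without replicate 2 of full stimulation. Of the named genes, 42 of 52 kept their call without each array, including each gene named for a rise or fall in the ionomycin effect at 4 h.

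In the ionomycin effect at 8 h CCL20 was at least 63.4-fold higher (2402 ± 34.9 against 76.55 ± 2.9), IL3 rose by 6.64 ± 0.29 (4399 ± 217 against 107 ± 1.27, adjusted p = 5.2e-09) and IFNG was at least 8.32-fold higher. HK2, the first enzyme of glycolysis, rose by 2.65 ± 0.19 (428 ± 8.13 against 122 ± 8.2), the glucose carrier SLC2A1 by 1.26 and the asparagine synthetase ASNS by 1.33. MYC stood 2.20 higher than in PMA with calcium, but under full stimulation it still lay below its untreated level. The costimulatory receptor genes TNFRSF4 and ICOS rose by 2.44 and 3.32, and CCND2 at least 12.6-fold. PI16, a protease inhibitor, fell by 4.03 ± 0.20 (131 ± 13.1 against 1162 ± 69.7, adjusted p = 1.6e-08), ADCYAP1 by 3.61, KLF2 by 2.59, the lineage factor GATA3 by 2.54 (202 against 866) and LAT by 1.76 ± 0.15 (2384 against 7866, adjusted p = 5.1e-06). TNF stood 0.75 ± 0.17 higher (899 ± 102 against 560 ± 25.8, adjusted p = 0.014), but lost its call without either replicate of PMA with calcium or replicate 2 of full stimulation. STIM1 differed by -0.67 (adjusted p = 0.085) and HSPA5 by -0.31 (adjusted p = 0.3).

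At 8 h, 13 of 33 NF-kB pathway and target genes rose with ionomycin and 4 fell (16 and 4 adjusted over the list alone, set adjusted p = 9.8e-08), NFKBIA by 1.32. Of 20 NFAT target and T cell cytokine genes 11 rose (12 adjusted over the list alone, set adjusted p = 1.1e-16). The T cell receptor and T lineage list shifted down, 1 of 22 higher and 5 lower (1 and 7 adjusted over the list alone, adjusted p = 0.0011). ATF4 and amino acid response genes shifted up, 4 of 22 higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 1.4e-04), with WARS1 up by 1.09. Interferon response genes had 2 of 21 higher and 1 lower (4 and 1 adjusted over the list alone, adjusted p = 0.0034), and cell cycle genes stood lower (2 of 29 higher and 1 lower, the same adjusted over the list alone, median -0.23, adjusted p = 0.013). The set call of glycolysis and hypoxia genes was lost with an estimated correlation (3 of 17 higher and 2 lower, 4 and 2 adjusted over the list alone, adjusted p = 0.017; adjusted p = 0.097 with an estimated correlation). The same held for T cell activation surface markers (6 of 19 higher and 3 lower, 7 and 4 adjusted over the list alone, adjusted p = 0.02; adjusted p = 0.062 with an estimated correlation) and unfolded protein response genes (1 of 23 higher, 1 adjusted over the list alone, adjusted p = 0.027; adjusted p = 0.059 with an estimated correlation).

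In the ionomycin effect at 8 h 935 genes passed, 438 higher and 497 lower, 206 and 222 of them by at least 2-fold. The count was 517 and 522 without replicates 1 and 2 of PMA with calcium and 623 and 498 without those of full stimulation. The glycolysis call ended without replicate 1 of full stimulation (adjusted p = 0.058) and the unfolded protein call without that array (0.068) or replicate 1 of PMA with calcium (0.074). Of 63 named genes 44 kept their call without each array, and besides TNF each gene named for a rise or fall at 8 h was among them.

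**Figure D2:**
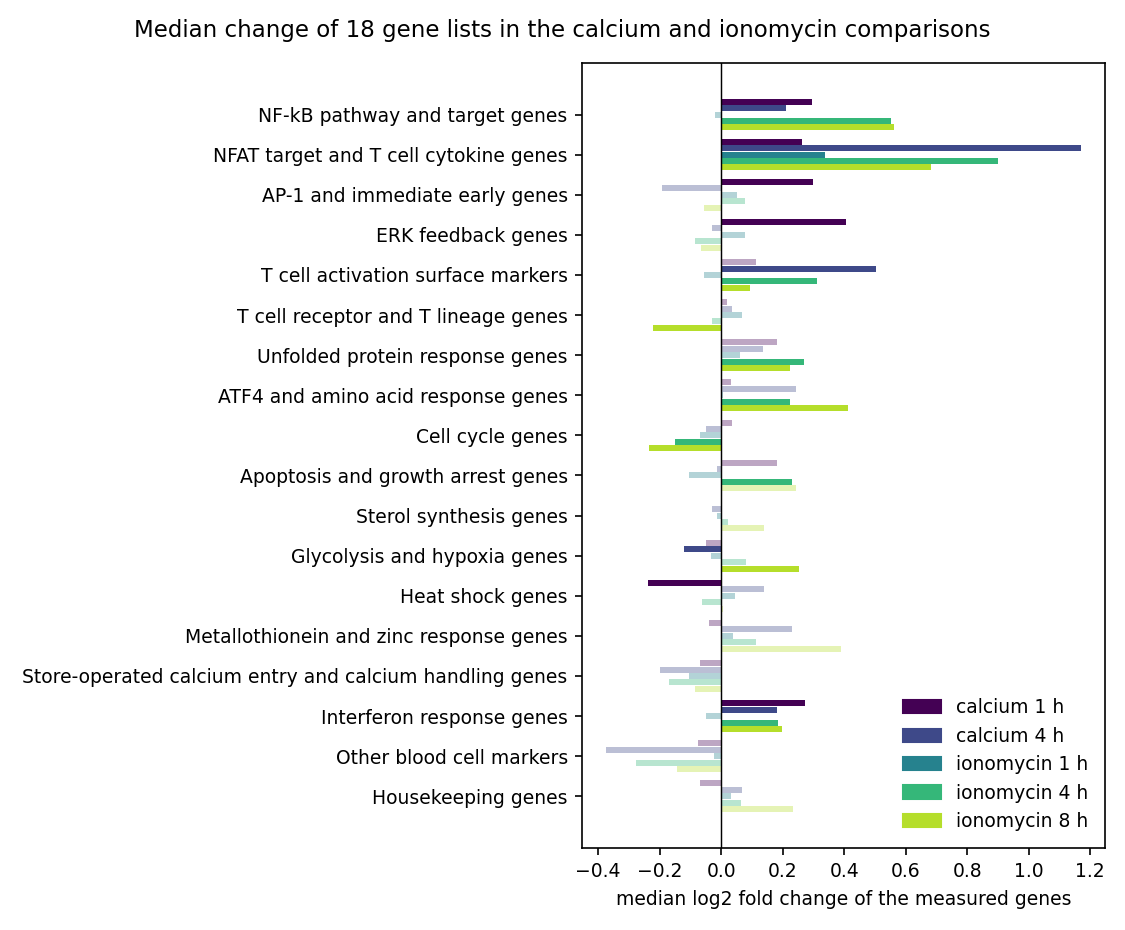
Median log2 fold change of the measured genes of 18 lists (horizontal axis) in the calcium effect at 1 and 4 h and the ionomycin effect at 1, 4 and 8 h, with pale bars where the set test did not pass. NFAT target and T cell cytokine genes reached 1.17 in the calcium effect at 4 h and 0.90 in the ionomycin effect at 4 h, and NF-kB genes stood at -0.02 in the ionomycin effect at 1 h.

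The calcium and ionomycin effects share the full stimulation arrays, so a chance reading of those arrays enters both. At 4 h, 145 genes were higher in both and 78 lower in both, where independent lists of these sizes would share 4.5 and 3.3. Simulated values without changes but with the shared arrays gave 0 and 0.01 on average over 100 draws. Few genes pass when nothing changes, so those simulated counts lie near 0 by design. They cannot show how much the shared arrays add to the overlap. The correlation across genes, which are not independent replicates, was 0.643 at 4 h against 0.501 in the simulation, and 0.203 at 1 h against 0.500. IL3, TNF, CCL20, GBP2 and NFKBIA were among the genes higher in both at 4 h, and KLF2 and UPP1 among those lower in both. At 1 h, 11 genes were higher in both and 0 lower in both.

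PMA with calcium and calcium-free stimulation differ in calcium, in EGTA and in ionomycin, and their comparison at 1 h was secondary. RGS16, a regulator of G protein signalling, stood 2.31 ± 0.20 higher on the log2 scale in PMA with calcium (254 ± 1.7 against 102 ± 1.06, adjusted p = 7.4e-05). HES1 stood 2.16 ± 0.18 higher (973 ± 16 against 267 ± 20) and GATA3 1.92 higher, while IER3, an NF-kB target that protects from apoptosis, stood 1.36 higher. TNF (-0.36, adjusted p = 0.21) and NFKBIA (0.39, adjusted p = 0.084) did not pass. Of 33 NF-kB pathway and target genes 9 stood higher (14 and 3 lower adjusted over the list alone, set adjusted p = 0.0011), a set call lost at adjusted p = 0.05 with an estimated correlation. AP-1 and immediate early genes had 8 of 29 higher and 4 lower (12 and 5 adjusted over the list alone, adjusted p = 0.039; adjusted p = 0.12 with an estimated correlation). Heat shock genes had 3 of 13 lower (4 adjusted over the list alone, adjusted p = 0.039; adjusted p = 0.32 with an estimated correlation), and both of these calls ended without replicate 1 of PMA with calcium (0.14 and 0.13) or replicate 1 of the calcium-free group (0.054 each).

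In that comparison 843 genes passed, 389 higher and 454 lower in PMA with calcium, among them 3 of 11 housekeeping genes lower. The count was 1433 without background correction, 1395 with an offset of 50, 1387 with a trend and robust settings and 33 with only the arrays compared. Higher genes led with the trend (724 and 663) and with a filter on 10 arrays (562 and 553). Over these 843 genes the log2 difference correlated at -0.788 with replicate 1 minus replicate 2 of full stimulation at 1 h, a group outside the comparison. The count was 32 without replicate 2 of PMA with calcium, 29 without replicate 1 and 228 without replicate 2 of the calcium-free group, and 7 of 48 named genes kept their call without each array: RGS16, HES1, KLF10, GATA3, TRIB1, LTA and IER3. NDUFB10, a subunit of mitochondrial complex I (-2.16, adjusted p = 0.008), and TRIM24 (-2.14, adjusted p = 0.015) lost theirs without replicate 2 of PMA with calcium or replicate 1 of the calcium-free group, and TRIM24 also without replicate 2 of the latter (0.061).

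At 4 h the same comparison gave differences in both directions. GZMB, lower in PMA with calcium, stood at -3.28 ± 0.25 (92.05 ± 17.2 against 364.5 ± 29.6, adjusted p = 9.2e-06), IFNG at -2.35 (111 ± 15.3 against 302 ± 50.1, adjusted p = 1.9e-04), TNF at -1.36 ± 0.17 (616 ± 4.81 against 1491 ± 183, adjusted p = 8.6e-04) and the CCL4L1 probe at least 20.4-fold lower. HSPA5 stood at -1.37 ± 0.15 (325.5 ± 2.55 against 742 ± 82.1, adjusted p = 2.8e-04). The chemokine CCL1 (2.11 ± 0.17, 225 ± 19.2 against 101 ± 7) and ADCYAP1 (1.90) stood higher, as did IL16, at least 5.26-fold. NF-kB genes shifted down (0 of 33 higher and 2 lower, 3 and 9 adjusted over the list alone, adjusted p = 0.0053). So did AP-1 genes (0 of 29 higher and 4 lower, 1 and 7 adjusted over the list alone, adjusted p = 0.007) and unfolded protein response genes (0 of 23 higher and 1 lower, 0 and 3 adjusted over the list alone, median -0.29, adjusted p = 0.0023). The same direction was seen for apoptosis and growth arrest genes (0 of 16 higher and 1 lower, 1 and 2 adjusted over the list alone, adjusted p = 0.007) and glycolysis and hypoxia genes (0 of 17 past the test, 1 lower adjusted over the list alone, adjusted p = 0.0044). The NFAT set also stood lower (1 of 20 higher and 4 lower, the same adjusted over the list alone, adjusted p = 0.012), except without replicate 1 of the calcium-free group (0.056). Cell cycle genes stood higher (0 of 29 passed, 1 higher adjusted over the list alone, adjusted p = 0.048; adjusted p = 0.066 with an estimated correlation), a call that ended without replicate 2 of PMA with calcium (0.14) or either calcium-free replicate (0.17 and 0.053).

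There 132 genes passed, 55 higher and 77 lower in PMA with calcium. Higher genes led with array weights (193 higher and 166 lower), a trend and robust settings (129 and 102) and a filter on 10 arrays (86 and 83). The count was 240 without background correction, 241 with an offset of 50 and 20 with only the arrays compared. The count was 46 and 52 without replicates 1 and 2 of PMA with calcium and 82 and 44 without those of the calcium-free group, and 13 of 22 named genes kept their call without each array, those named at 4 h among them.

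Untreated cells served as the reference for every time, so time in the buffer is part of each comparison with them. They were listed at 0 mM calcium. The 2 mM calcium outside the cells is therefore also part of their comparisons with PMA with calcium and full stimulation. After 1 h the immediate early gene EGR1 rose by 6.04 ± 0.14 in PMA with calcium (23850 ± 1540 against 425 ± 0.42, adjusted p = 1.2e-11), by 5.91 under full stimulation and by 6.07 under calcium-free stimulation. FOS, an AP-1 subunit, rose at least 35.2-fold, 79.7-fold and 71.0-fold. CD69, an early activation marker, rose by 5.28, 6.77 and 5.69, and NFKBIA by 3.33, 4.20 and 2.93. TNF rose by 3.36, 6.47 and 3.72. HSPA1B, a heat shock chaperone, fell by 1.74 ± 0.23 in PMA with calcium and by 1.69 under full stimulation. MYCN fell by 3.01 under calcium-free stimulation.

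Of 29 AP-1 and immediate early genes 16 rose at 1 h in each stimulation, while 3, 1 and 4 fell in PMA with calcium, full and calcium-free stimulation (19 and 3, 17 and 4, and 16 and 4 adjusted over the list alone; set adjusted p = 5.3e-21, 9.6e-30 and 2e-12). Of 33 NF-kB genes 12, 13 and 8 rose and 0, 1 and 1 fell (16 and 1, 14 and 2, and 11 and 2 adjusted over the list alone; set adjusted p = 1.5e-14, 4.5e-18 and 2.8e-07). Of 17 ERK feedback genes 8, 8 and 6 rose (8, 8 and 7 adjusted over the list alone; set adjusted p = 1.1e-10, 9.2e-18 and 2.7e-07). The NFAT and T cell cytokine set passed under full stimulation (4 of 20 rose, 5 adjusted over the list alone, adjusted p = 6.5e-07) and not in PMA with calcium (1 rose, adjusted p = 0.9) or calcium-free stimulation (1 rose, adjusted p = 0.31); the difference between stimulations was tested in the calcium and ionomycin effects at 1 h. Genes past the test numbered 316 in PMA with calcium (216 higher and 100 lower), 153 under full stimulation (121 and 32) and 621 under calcium-free stimulation (343 and 278). The first was 104 without untreated replicate 2 and 95 without replicate 2 of its group, the second 88 without untreated replicate 2, and the third 99 without untreated replicate 2 and 92 and 255 without replicates 1 and 2 of its group, while each gene named here at 1 h kept its call in these runs. With only the arrays compared they were 38, 32 and 25, and array weights gave 164 and 86 for the first and second. The first was 559 without background correction, 582 with an offset of 50 and 642 with a trend and robust settings. In the third, lower genes led with the trend (459 higher and 469 lower) and with a filter on 10 arrays (400 and 416).

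After 4 h LTB, a cytokine of lymphoid organ formation, had risen by 5.98 ± 0.22 in PMA with calcium (6848 ± 160 against 175 ± 42.7, adjusted p = 9.4e-10), CDKN1A, which blocks the cell cycle, by 5.97 ± 0.28 and the phosphatase DUSP5 by 5.37. Calcium-free stimulation gave CDKN1A 6.17 and DUSP5 5.97, while full stimulation gave IL3 at least 61.4-fold, TNF 6.47 ± 0.17 and IFNG at least 17.1-fold. MYC fell by 2.50 in PMA with calcium (1013 against 5394, adjusted p = 5.6e-06) and SMAD6, an inhibitor of BMP signalling, by 2.91 there and by 3.18 under full stimulation. RCAN1, a calcineurin regulator, fell by 1.09, 1.24 and 0.75 in PMA with calcium, full and calcium-free stimulation. Of 33 NF-kB genes 20, 22 and 21 rose and 1, 0 and 0 fell (20 and 2, 25 and 1, and 24 and 1 adjusted over the list alone; set adjusted p = 4.4e-15, 1.2e-23 and 1.9e-18). Of 20 NFAT and T cell cytokine genes 7, 12 and 9 rose and 1, 1 and 2 fell (7 and 2, 13 and 2, and 9 and 3 adjusted over the list alone; set adjusted p = 0.052, 1.8e-11 and 0.0024). Of 23 unfolded protein response genes 5 rose and 3 fell in PMA with calcium, without a set shift (5 and 5 adjusted over the list alone, median 0.05, adjusted p = 0.67), whereas 6 rose under full and 6 under calcium-free stimulation (6 each adjusted over the list alone, adjusted p = 9.3e-05 and 0.0077). Genes past the test numbered 2050 (1066 higher), 2134 (989 higher) and 2361 (1094 higher). They were 931, 1039 and 1366 without untreated replicate 2, 910 and 1088 without replicates 1 and 2 of PMA with calcium, 1332 and 1401 without those of full stimulation, and 1466 and 1439 without those of calcium-free stimulation. Genes named here kept their call in these runs. Under full stimulation higher genes led with cyclic loess (1079 higher and 987 lower) and with only the arrays compared (619 and 502). Calcium-free stimulation gave 1175 higher and 1174 lower with cyclic loess. In PMA with calcium lower genes led with a trend and robust settings (1197 and 1213).

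After 8 h in PMA with calcium 16 of 21 interferon response genes rose and 0 fell (16 adjusted over the list alone, median 1.36, set adjusted p = 6.6e-12), GBP2 at least 31.0-fold and GBP1 by 5.20. Under full stimulation 17 rose (18 adjusted over the list alone, set adjusted p = 5.2e-15), GBP2 at least 158-fold (5908 ± 239 against 84.15 ± 8.41), the antiviral synthetase OAS3 by 3.38 and TAP1 by 3.44. NF-kB genes numbered 20 higher and 1 lower of 33 in PMA with calcium and 25 and 0 under full stimulation (20 and 2, and 26 and 0 adjusted over the list alone; set adjusted p = 3.8e-13 and 3.9e-20). Unfolded protein response genes numbered 9 higher and 1 lower of 23 (12 and 1 adjusted over the list alone, adjusted p = 1.1e-05) and 16 and 0 (17 and 0 adjusted over the list alone, adjusted p = 1.9e-08). Of 29 cell cycle genes 14 fell and 4 rose under full stimulation (15 and 4 adjusted over the list alone, set adjusted p = 0.0035), and 4 of 8 metallothionein and zinc response genes rose (5 adjusted over the list alone, adjusted p = 0.0068), among them MT2A by 1.82. PMEPA1, which restrains TGF-beta signalling, fell by 3.78 and 4.15, and MYC by 3.46 in PMA with calcium (548 against 5394, adjusted p = 1.3e-07). Genes past the test numbered 2820 (1415 higher) and 3070 (1453 higher), and were 1652 and 1832 without untreated replicate 2, 1605 and 1719 without replicates 1 and 2 of PMA with calcium, and 1936 and 2035 without those of full stimulation. Each gene named here at 8 h kept its call in these runs. The direction that led turned under 5 settings in PMA with calcium, to at lowest 1465 higher and 1517 lower with a filter on 10 arrays. Under full stimulation it turned with cyclic loess (1536 and 1528) and the mean of probes (1504 and 1456).

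The calcium-free 8 h array enters 4 comparisons. Their counts rest on an array that ranked probes unlike all the others, and are not read as gene changes. They were 9869 genes in the calcium effect at 8 h, 9837 against PMA with calcium, 9568 against untreated cells and 9438 in the calcium effect at 8 h against 4 h. The median of all genes moved by 1.67, 1.66, -1.60 and 1.71 on the log2 scale, and 77.6% of the genes in the calcium effect at 8 h were higher with calcium, against 35.4% after cyclic loess normalization.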

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

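The changes of the ionomycin effect over time, the test on replicate arrays at 1 h, the 3 tests of the unfolded protein response and the tests of normalization and of a swap for the calcium-free 8 h array were chosen after the result was seen.

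The calcium effect differed between 4 and 1 h in 347 genes by a test of the difference, 189 higher and 158 lower at 4 h. Of the named genes that had passed at either time, 41 passed this test, IL3 and KLF2 among them, and 8 genes passed in opposite directions at the 2 times: BHLHE40, DUSP5, FOSB, NAB2, PGRMC2, SGK1, TFE3 and WT1, those outside the naming rule chosen after their values were seen. The median difference was 0.55 for NFAT target and T cell cytokine genes and -0.70 for AP-1 and immediate early genes, which turn on within minutes of a stimulus. It was -0.25 for ERK feedback genes (adjusted p = 0.043; adjusted p = 0.13 with an estimated correlation) and 0.27 for heat shock genes (adjusted p = 0.0099; adjusted p = 0.23 with an estimated correlation). The ERK call ended without replicate 1 of full stimulation at 1 h (0.18), replicate 2 of the calcium-free 1 h group (0.14), replicate 1 of full stimulation at 4 h (0.063) or replicates 1 and 2 of the calcium-free 4 h group (0.091 and 0.069), and the heat shock call without replicate 2 of full stimulation at 1 h (0.13).

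The ionomycin effect differed between 4 and 1 h in 170 genes, 102 higher and 68 lower at 4 h, with 34 named genes past the test and 1 gene, FOS, in opposite directions. List medians differed by 0.42 for NF-kB genes and 0.46 for NFAT target and T cell cytokine genes, by 0.25 for unfolded protein response genes (0.246, adjusted p = 0.0027), and by 0.25 for apoptosis and growth arrest genes (0.251) and 0.17 for interferon response genes (adjusted p = 0.046 each; adjusted p = 0.084 each with an estimated correlation). T cell activation markers had a median difference of 0.00519 (adjusted p = 0.049; adjusted p = 0.12 with an estimated correlation). Between 8 and 4 h the ionomycin effect differed in 41 genes, 18 higher and 23 lower, 13 of them named, among them CCL20, TNF and HSPA5. Medians differed by -0.25 for the T lineage list and 0.26 for ATF4 and amino acid response genes (adjusted p = 0.012; adjusted p = 0.07 each with an estimated correlation), and by 0.07 for glycolysis and hypoxia genes (0.0705, adjusted p = 0.012; adjusted p = 0.12 with an estimated correlation).

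At 1 h 843 genes differed between PMA with calcium and calcium-free stimulation. A response to the calcium-free medium lasting to 4 h predicted a positive correlation between the times, but the contrast at 4 h correlated at -0.299 with that at 1 h over these genes. They were chosen by their 1 h values, which array differences may have set in part. The value therefore cannot exclude a lasting response in some of them. Differences between arrays that no treatment sets may account for part of them: replicate 1 minus replicate 2 of full stimulation at 1 h, 2 arrays treated alike, correlated at -0.788 with the contrast. This correlation was negative in all 9 replicate pairs, from -0.788 to -0.0384, with -0.606 and -0.528 for the 8 h pairs of full stimulation and PMA with calcium. A response that ends before 4 h stays open.

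Unfolded protein response genes stood higher with ionomycin than with PMA and calcium at 4 h. For calcium-free stimulation the median over PMA with calcium was 0.285. A reading of 1 array is argued against there, since the highest adjusted p without each of 4 arrays was 0.018. An effect of ionomycin without calcium from outside and a low reading of both PMA with calcium arrays cannot be told apart. The 0.285 only restates the pattern, and the median of PMA with calcium against untreated cells, 0.0533, lies between the bounds set for and against a low reading. Release of stored calcium by the ionophore was not tested.

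The calcium-free 8 h array ranked probes unlike every other array. Normalization between arrays and a swap within the series are both argued against by its highest rank correlation of 0.105, under the lowest (0.751) among the other 18. That value is the pattern itself, so it is no separate test of either. Values set against the wrong probes are argued against by a median rank correlation of 0.168 over 19296 dim probes, where the other arrays had a median of 0.238. A lack of labelled material on that array stays open and was not tested, and no biological explanation was tested.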

How the results depend on the processing

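Leaving out replicates was planned; normexp with its background estimated from all values and the run without the calcium-free 8 h array were chosen after seeing the data. On 18 arrays 33.9% to 34.4% of probes stood above background, which limits dim genes. A group left with 1 array is assumed to vary like the others. A chip block (no chip is known for a sample) and the non-normalized signals were not run. Set results followed here include the NF-kB list in the ionomycin effect at 1 h, which did not pass. With an estimated correlation 79 kept their outcome and 16 lost a call. Over all runs without 1 replicate 363 kept it and 33 lost a call. Named-gene results, with or without a call, kept their outcome in 3171 such runs, lost a call in 675 and gained one in 6. The changes of the ionomycin effect over time were not run under the alternatives. All 20 counts stayed within 1.5 times without a filter, with scaling to the 75th percentile, with the mean of a gene's probes and with the background estimated from all values. Named-gene calls lost numbered 194 with only the arrays compared, 40 with array weights, 35 with the mean of probes, 31 without a filter, 24 with the background from all values, 23 without background correction, 15 with a trend, 14 with an offset of 50, 7 with cyclic loess, 4 with the block, 2 with scaling to the 75th percentile and 1 without the calcium-free 8 h array. With the filter on 10 arrays 808 named-gene results kept their outcome and 10 gained a call. Named genes that this filter removed, or that fell out with only the arrays compared, were not tested there and are not among the losses. Set calls lost numbered 9 with only the arrays compared, 8 with the filter on 10 arrays, 7 with the mean of probes, and 1 each without background correction, with the block and without the calcium-free 8 h array.

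The causes of the following were not tested, except that fewer arrays leave fewer degrees of freedom. Without background correction the calcium effect gave 419 genes at 1 h (45.3% higher, against 56.9%) and its change from 1 to 4 h 611, the ionomycin effect at 1 h 41 (56.1% higher, against 73.9%), PMA with calcium against calcium-free stimulation 1433 at 1 h and 240 at 4 h, and PMA with calcium against untreated at 1 h 559. In the same order an offset of 50 gave 399 (46.9%), 604, 43 (60.5%), 1395, 241 and 582, and a trend with robust settings 440 (49.1%), 592, 54 (55.6%), 1387, 231 (55.8% higher, against 41.7%) and 642 (57.9% higher, against 68.4%). A filter on 10 arrays gave 235 in the calcium effect at 1 h, and the ionomycin effect at 1 h was then 58.6% higher. Deviations of same-numbered arrays correlated between -0.083 and 0.217 over 36 pairs of groups (median 0.0342, 9 over 0.1), short of the rule for pairing, each over 0.1, and no label ties the numbers. As a hint from the data, 0 fell under -0.1. A replicate block gave 380 in the calcium effect at 1 h, 154 higher and 226 lower (40.5% higher), against 74 and 56, and 538 in its change to 4 h. Array weights gave 47 (76.6% higher) and 225 there, 9 in the ionomycin effect at 1 h, 359 (53.8% higher) in PMA with calcium against calcium-free stimulation at 4 h, and against untreated at 1 h 164 for PMA with calcium and 86 (90.7% higher, against 79.1%) for full stimulation.

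With only the arrays compared, the calcium effect gave 2 genes at 1 h, 127 at 4 h and 83 for its change, the ionomycin effect at 1 h 2, PMA with calcium against calcium-free stimulation 33 (24.2% higher, against 46.1%) and 20 (25.0% higher) at 1 and 4 h, and against untreated 38 (PMA with calcium, 1 h), 32 and 1121 (full stimulation, 1 and 4 h) and 25 (calcium-free, 1 h), where GADD45A reversed to -0.07 (-0.0678). Cyclic loess gave 6035, 5935, 5821 and 4825 in the 4 comparisons with the calcium-free 8 h array, moving the share higher from 77.6%, 77.5%, 23.2% and 77.7% to 35.4%, 35.4%, 66.3% and 26.4%. Without a filter these shares were 59.8%, 59.8%, 41.0% and 60.4%.

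Without each replicate in turn the calcium effect ran from 26 to 563 genes at 1 h, 218 to 341 at 4 h and 9484 to 9528 at 8 h, its change from 124 to 650 (4 against 1 h) and 9159 to 9366 (8 against 4 h). The ionomycin effect ran from 11 to 134, 193 to 284 and 498 to 623 at 1, 4 and 8 h, and PMA with calcium against calcium-free stimulation from 29 to 982, 44 to 82 and 9530 to 9552. Against untreated, PMA with calcium ran from 95 to 298, 910 to 1538 and 1605 to 2344, full stimulation from 88 to 179, 1039 to 1691 and 1832 to 2574, and calcium-free stimulation from 92 to 442, 1366 to 1766 and 9378 to 9406.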

Other observations

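The tests in this part were planned, and 0 were chosen after the result was seen.

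ATF4 and amino acid response genes, which meet a shortage of amino acids, were higher than in untreated cells as a set in part of the comparisons. At 4 h 11 of 22 rose and 3 fell under full stimulation (13 and 3 adjusted over the list alone, median 0.52, adjusted p = 6.3e-04). In PMA with calcium 8 rose and 2 fell (10 and 3 adjusted over the list alone, adjusted p = 0.046; adjusted p = 0.082 with an estimated correlation), a call lost without untreated replicate 1 (0.13) or replicate 2 of PMA with calcium (0.051). At 8 h of full stimulation 12 rose and 4 fell (13 and 5 adjusted over the list alone, median 0.82, adjusted p = 0.0017). The set did not pass in PMA with calcium at 8 h (7 rose and 3 fell, 9 and 3 adjusted over the list alone, adjusted p = 0.27) or calcium-free stimulation at 4 h (9 and 2, 9 and 3 adjusted over the list alone, adjusted p = 0.062). Nor did it at 1 h in PMA with calcium (adjusted p = 0.38), full (0.51) or calcium-free stimulation (0.31).

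ERK feedback genes stood higher than in untreated cells after each stimulation at 4 h and after PMA with calcium and full stimulation at 8 h. In PMA with calcium 9 of 17 were higher and 0 lower at 4 h (10 adjusted over the list alone, adjusted p = 8e-09) and 12 and 0 at 8 h (12 adjusted over the list alone, adjusted p = 9.1e-11). Under full stimulation 10 were higher and 1 lower at 4 h (the same adjusted over the list alone, adjusted p = 8.8e-10) and 11 and 0 at 8 h (11 and 1 adjusted over the list alone, adjusted p = 1.3e-09). Under calcium-free stimulation 8 were higher and 1 lower at 4 h (9 and 1 adjusted over the list alone, adjusted p = 8.3e-08). T cell activation surface markers numbered 10 of 19 higher and 2 lower after 8 h of full stimulation (the same adjusted over the list alone, adjusted p = 3.1e-06), and 9 and 2 in PMA with calcium (the same adjusted over the list alone, adjusted p = 6.7e-04). At 4 h they numbered 8 and 1 under full stimulation (the same adjusted over the list alone, adjusted p = 1.2e-05), 9 and 1 under calcium-free stimulation (10 and 2 adjusted over the list alone, adjusted p = 0.002) and 7 and 2 in PMA with calcium (the same adjusted over the list alone, adjusted p = 0.0091; adjusted p = 0.056 with an estimated correlation). STIM1, the calcium sensor of the endoplasmic reticulum, stood 1.00 ± 0.21 higher after 8 h in PMA with calcium than in untreated cells (adjusted p = 0.0043), but lost its call without untreated replicate 2.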
